A study of Mus musculus with 2 samples.

How the data were processed

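The data are single-cell RNA sequencing of live CD45+ cells sorted from collagenase-digested skin, per the labels' protocols, with 1 library of an isotype control pool and 1 of an anti-Gr-1 pool. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, made by the authors with Cell Ranger 4.0.0 per the file headers and aligned to mouse build mm10 per the submitters' processing notes. The labels write the build as mms10. The files hold barcodes that had already been called as cells, with at least 500 UMIs each, and the same 32285 genes in both libraries. The labels' protocols name the 3′ v2 chemistry and antibody-derived tags; tags were not used here. Groups were taken from the treatment label of each library.

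Cells were handled in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and umap 0.5.12, and plots were drawn with matplotlib 3.10.9. Barcodes with at least 200 genes, at least 500 UMIs and under 10% mitochondrial UMIs were taken further, which left 19542 of 21311 isotype control and 8047 of 9110 anti-Gr-1 barcodes. Doublets were scored per library with scrublet in scanpy. Its automatic threshold called 43.3% of the isotype control barcodes, above the limit of 25% fixed beforehand, so the 3055 barcodes with the highest scores were removed there, at an expected rate of 0.8% per 1000 barcodes. In the anti-Gr-1 library the automatic threshold removed 524 barcodes (6.51%). The kept cells numbered 16487 and 7523. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, without mitochondrial, haemoglobin and sex-linked check genes, gave 30 principal components and a graph of 15 neighbours. Leiden clustering at resolution 1.0 was run on both libraries together without integration, and lymphoid and mononuclear phagocyte clusters were clustered again apart at resolution 1.0.

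Clusters were named by marker lists fixed before the data were examined, but the rule for assigning a name was set after the clusters were seen. A cluster took a class name with a mean log2 marker score of at least 0.6, at least 4 markers found in 30% of its cells or more, and a marker among its 10 leading genes. Its leading genes could hold no more markers of another class than of its own. A cluster in which both genes of a pair from different lineages, such as Cd3e and Mgl2, were each found in at least 40% of cells was set aside as mixed. This named 27 of 45 clusters in 19 classes. The unassigned ones include the lymphoid cluster L4, led by Hlf, Bmp2 and Rora (7.05% of isotype control and 10.5% of anti-Gr-1 cells), the myeloid clusters M2 (3.10% and 3.46%) and M0 (1.75% and 1.77%) that express Lpl, Fn1 and Retnla, and 8 mixed clusters (2657 and 110 cells). Monocyte-like cells are the classical and non-classical classes together. Cells with Xist UMIs and none from 4 Y-linked genes were called female and the reverse male.

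With 1 library per group no test was made. Shares of kept cells have 95% Clopper-Pearson intervals, and ratios of shares or of CPM have exact conditional intervals. UMIs were summed over the cells of a class and given as CPM of that class, and log2 ratios used a pseudocount of 5 CPM. The gene lists were fixed before the data were examined. A list's value is the median log2 ratio of its members with at least 20 UMIs over both libraries, with its percentile among 10000 random lists matched on expression. Its counting range comes from redrawing the counts. For each gene and library, the level of free RNA was taken as the lowest value among 9 large classes, and a gene was called above it at 3 times that level or more. A count of 0 was set to a floor of 3 counts where a bound was needed. Genes were named by a rule fixed beforehand: in each of 6 classes with at least 100 cells per library, the 10 highest and 10 lowest log2 ratios among genes with at least 50 UMIs and at least 50 CPM in 1 library. That rule left out mitochondrial, ribosomal, haemoglobin, immunoglobulin and receptor segment genes, unnamed models, sex-linked check genes, the markers of the class itself and markers of free RNA. It also names Il1b, Il1rn, Il1r1, Il1r2 and Il17a in every class and up to 4 list members with the largest ratios. Ifng, S100a8, Retnla, Folr2, Itgal, Il1a, Il6, Il23a and a few other single genes outside it were chosen after their values were seen. Monocyte-like and neutrophil-like cells had fewer than 100 cells in the anti-Gr-1 library and were given no named genes. Gene positions came from GENCODE M21 on mm10, which holds 99.6% of the files' gene identifiers.

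Scripts were tested on simulated data. With 200 genes of macrophage-like cells changed by known folds among 8813 genes, the median recovered log2 ratio was 1.95 for a 4-fold and -0.99 for a 0.5-fold change, and the intervals of the 8613 genes left alone covered the true ratio in 96.0% of cases. Intervals of share ratios covered the truth in 96% of 1000 simulated ratios. The simulated counts were drawn independently, as the intervals assume, so this coverage checks the code only. It does not speak for real UMIs that lie together in few cells. Alternatives tried were other clustering resolutions, stricter filters, doublets kept, each library clustered alone, thinning to 1000 UMIs, each sex apart, other pseudocounts and scalings, no filter on low counts and equal weight per cell. Chosen after the data were seen were a minimum of 2000 UMIs, leaving out mixed clusters or counting them with their best-scoring class, macrophage-like or gamma-delta cells alone, members above free RNA, subtraction of the lowest class level, and 3 of 5 marker gates; the cutoffs of all 5 gates were set after the data were seen. One criterion was altered once its value was known. A check for free RNA in T cells first asked for mast cell markers with an upper end under 0.8 in each of 4 classes and counted a miss as evidence against free RNA. Regulatory T cell-like cells missed it, and the check now leaves the question open in that case. Replacement checks in mast cell-like and type 2 dendritic-like cells, picked when their values were known, were tried and dropped.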

Results

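Live CD45+ cells were sorted from the skin of C57BL/6 mice at postnatal day 15 and profiled by droplet-based single-cell RNA sequencing of 3′ ends. The mice had been given anti-Gr-1, an antibody that binds the surface proteins Ly6G and Ly6C of neutrophils and monocytes, or an isotype control antibody, every other day from day 4 to day 14. Cells of 4 to 7 mice were pooled per treatment, and each pool gave 1 library, so there are no replicates and no difference between the groups was tested. The isotype control library held 21311 barcodes with 125253392 UMIs in total and a median of 4460 UMIs per barcode. The anti-Gr-1 library held 9110 barcodes with 85142470 UMIs and a median of 7463. After filtering, 16487 isotype control cells (103077414 UMIs, median 5073) and 7523 anti-Gr-1 cells (73873647 UMIs, median 7865) were kept. Intervals in parentheses after a share are 95% Clopper-Pearson intervals and those after a count or a ratio are exact Poisson or conditional intervals. All of them cover counting error only, not the difference between mice or, for UMIs, the spread between cells of a class. Cell classes carry the ending "-like" because they rest on marker genes alone. Clusters that could not be assigned to a class by a threshold set after the data were seen held 34.2% of the isotype control cells and 24.8% of the anti-Gr-1 cells.

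The study design states that the antibody was meant to deplete monocytes, and the genes of its targets were looked at before any other. Ly6c2, which encodes the Ly6C protein of inflammatory monocytes, was lower in the anti-Gr-1 library, at 9.79 CPM (UMIs scaled to the same total in every library or class) against 36.7 (ratio 0.266, 0.246 to 0.289). Ly6c1, a close relative found on endothelial and some lymphoid cells, had 74 UMIs against 175 (ratio of CPM 0.590, 0.443 to 0.779). Ly6g, the neutrophil target, was hardly captured in either library, with 27 UMIs in 13 isotype control cells and 37 UMIs in 5 anti-Gr-1 cells. Its ratio of 1.91 (1.13 to 3.27) turned to 0.879 when each cell was given equal weight. All but 1 of the isotype control Ly6g UMIs and all 37 of the anti-Gr-1 ones lay in neutrophil-like and monocyte-like cells. Some cells with Ly6g RNA thus remained in the anti-Gr-1 library. Ly6c2 UMIs were found in 4.68% of the isotype control cells and 2.11% of the anti-Gr-1 cells, although the anti-Gr-1 cells were sequenced more deeply. Outside the neutrophil-like and monocyte-like classes, Ly6c2 was also lower, at 7.01 against 24.7 CPM (ratio 0.284, 0.258 to 0.312). In the files' annotation these genes are Ly6c2 (ENSMUSG00000022584), Ly6c1 (ENSMUSG00000079018) and Ly6g (ENSMUSG00000022582), which lie on mouse chromosome 15 of build mm10 at 75108158 to 75111970, 75044018 to 75048830 and 75155240 to 75159126.

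Both myeloid populations that carry the targets were scarce in the anti-Gr-1 library. Neutrophil-like cells made up 1.74% (1.55 to 1.95) of the isotype control cells, 287 in number, and 0.160% (0.0824 to 0.278) of the anti-Gr-1 cells, 12 in number, a ratio of 0.0916 (0.0468 to 0.163). Classical monocyte-like cells, the Ly6C-high blood monocytes that enter tissue, made up 3.12% against 0.306%, a ratio of 0.0981 (0.0616 to 0.149). Non-classical monocyte-like cells, the patrolling kind with little Ly6C, were less unequal, at 0.752% against 0.319% (ratio 0.424, 0.262 to 0.661). Monocyte-like cells of both kinds together were 3.87% (3.58 to 4.18) of the isotype control and 0.625% (0.459 to 0.830) of the anti-Gr-1 cells, a ratio of 0.161 (0.117 to 0.217). An unassigned cluster of mixed markers led by interferon-induced genes and Ly6c2 held 104 and 13 cells. S100a8, a calcium-binding protein abundant in neutrophils, had almost the same level in both libraries, 138 and 135 CPM, of which the neutrophil-like class gave 96.6% and 98.2%. The 12 anti-Gr-1 neutrophil-like cells had a median of 5068.5 UMIs and the 287 isotype control ones a median of 1702. The depths of the libraries differed: 22.1% of the isotype control cells and 4.40% of the anti-Gr-1 cells had under 2000 UMIs, and among deeper cells the neutrophil-like ratio was 0.167 (0.0809 to 0.309). Counting cells by 3 monocyte marker genes without clusters moved the monocyte-like ratio to 0.252 for the classical kind and 0.295 for both kinds.

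Among the other named classes, the shares of type 1 dendritic cells and of conventional CD4 T cells differed the most. Type 1 dendritic-like cells, which present antigen to CD8 T cells, were 3.02% of the isotype control cells and 7.06% of the anti-Gr-1 cells (ratio 2.34, 2.06 to 2.65). Conventional CD4 T cell-like cells numbered 248 in the isotype control and 247, or 3.28%, in the smaller anti-Gr-1 library (ratio 2.18, 1.82 to 2.61), and mast cell-like cells were 3.04% against 5.01% (ratio 1.65, 1.44 to 1.88). The mast cell-like direction turned to a ratio of 0.829 (0.735 to 0.934) when mixed clusters were counted with the class they scored highest for, since a mixed cluster led by mast cell genes held 497 isotype control cells and 1 anti-Gr-1 cell. Dermal gamma-delta T cell-like cells of the type 17 kind, the main early source of IL-17 in skin, were 10.4% against 15.1% (ratio 1.46, 1.35 to 1.57). Dendritic epidermal T cell-like cells, the gamma-delta T cells of the epidermis, were 15.4% against 19.0% (ratio 1.23, 1.16 to 1.32), but 0.999 (0.864 to 1.15) among female cells. Shares of regulatory T cell-like cells (3.53% and 3.92%), type 2 dendritic-like cells (10.2% and 10.5%), Langerhans-like cells (1.01% and 0.891%) and group 2 innate lymphoid-like cells (1.31% and 1.58%) were closer. Macrophage-like cells were lower in the anti-Gr-1 library, at 3.83% against 5.40% (ratio 0.709, 0.619 to 0.811), and so were B cell-like cells, at 0.306% against 0.643%. The unassigned clusters M2 and M0, with Fn1 and Lyz2 among their leading genes, are not in the macrophage-like class. Their ratios were 1.12 (0.957 to 1.30) and 1.01 (0.818 to 1.25). All T cell classes together were 31.1% against 41.8% (ratio 1.34, 1.28 to 1.40). Shares of 1 library sum to the whole, but without neutrophil-like and monocyte-like cells in the denominator the ratios stayed above 1, at 1.28 for T cells, 2.22 for type 1 dendritic-like and 2.08 for conventional CD4 T cell-like cells. Unassigned clusters with markers of several lineages took up 16.1% of the isotype control cells and 1.46% of the anti-Gr-1 cells. With those cells left out, the T cell ratio was 1.14. Both Xist and Y-linked UMIs were found in 1218 of the 16487 isotype control and 223 of the 7523 anti-Gr-1 cells. Doublets left in the named classes may thus differ between the libraries, and their part in differences within classes was not tested. With each mixed cluster counted under its best-scoring class, type 2 dendritic-like cells were 21.3% against 11.6% (ratio 0.545) and macrophage-like cells 6.65% against 3.96% (ratio 0.595). With doublets kept and clusters redrawn, the same ratios were 1.40 (1.25 to 1.57) and 0.926, the latter with an upper end of 1.07. Within T cell-like cells, the conventional CD4 share was 4.84% in the isotype control and 7.86% in the anti-Gr-1 library, the regulatory share 11.4% and 9.39%, the gamma-delta type 17 share 33.4% and 36.2%, and the dendritic epidermal share 49.6% and 45.6% (ratio 0.919, 0.861 to 0.981).

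**Figure D1:**
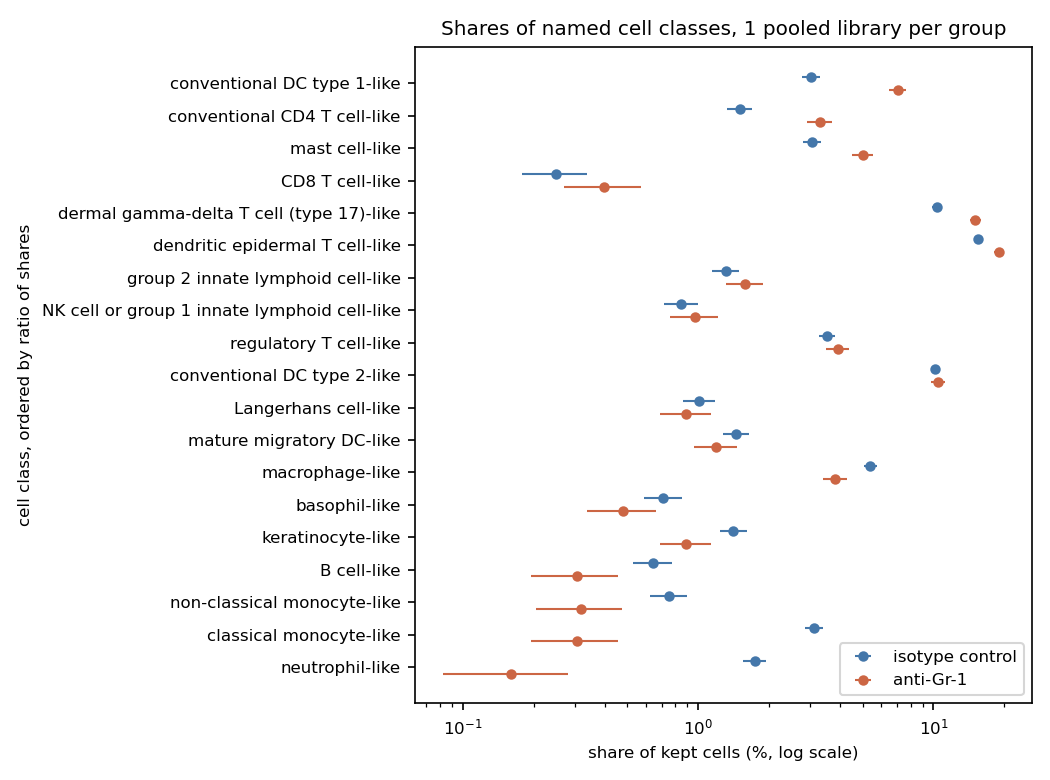
Share of kept cells in percent on a log axis for each named class, ordered by the ratio of the anti-Gr-1 (orange) to the isotype control share (blue), with 95% Clopper-Pearson bars that cover counting error only, 1 pooled library each. Neutrophil-like cells stand at 1.74% and 0.160%, type 1 dendritic-like cells at 3.02% and 7.06%.

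The title of the series names crosstalk of myeloid cells and type 17 inflammation, which directs attention to interleukin-1 and its brakes. Il1b, the inflammatory cytokine interleukin-1 beta, was lower in anti-Gr-1 than in isotype control macrophage-like cells, at 400 against 716 CPM (ratio 0.559, 0.522 to 0.597). Cd209a, a marker of type 2 dendritic cells, was lower in these macrophage-like cells too (ratio 0.477, 0.398 to 0.569). Whether RNA of type 2 dendritic cells adds to their Il1b was not tested. In the few monocyte-like cells left, Il1b was also lower, at 1600 against 3380 (ratio 0.473, 0.438 to 0.510). The classical kind made up 514 of 638 isotype control but 23 of 47 anti-Gr-1 monocyte-like cells. Within the classical kind the Il1b ratio was 0.513 (0.470 to 0.558), and within the non-classical kind it was 0.638 (0.535 to 0.756). Il1rn, the receptor antagonist that blocks interleukin-1, was also lower in macrophage-like cells, at 87.4 against 127 (ratio 0.688, 0.592 to 0.798), and in monocyte-like cells, at 219 against 338 (ratio 0.648, 0.522 to 0.796). Within the classical kind its ratio was 0.842 (0.679 to 1.04), and after thinning to 1000 UMIs the ratio in monocyte-like cells was 0.223 (0.0455 to 0.662), from 3 UMIs in 46 and 176 in 601 cells. Il1r2, a decoy receptor that captures interleukin-1, had 2 UMIs in anti-Gr-1 and 70 in isotype control macrophage-like cells (ratio 0.0574, 0.00682 to 0.215). Type 2 dendritic-like cells, the largest source of Il1b in both libraries, had nearly equal levels of Il1b (3917 and 3962, ratio 1.01) and of Il1rn (133 and 126, ratio 0.947). By sex, the directions were opposite in these cells, which was not tested: Il1b had a ratio between 0.780 and 0.820 in female cells and of 1.07 (1.05 to 1.09) in male cells, and Il1rn 0.833 (0.732 to 0.946) and 1.14 (1.04 to 1.24). They gave 53.9% of all Il1b UMIs in the isotype control and 68.1% in the anti-Gr-1 library, while classical monocyte-like cells gave 10.9% in the isotype control. Over all kept cells Il1b was 1205 against 950 CPM (ratio 0.788) and Il1rn 93.3 against 52.7 (ratio 0.565), isotype control given first. In the annotation Il1b (ENSMUSG00000027398) lies on chromosome 2 at 129364570 to 129371139, Il1rn (ENSMUSG00000026981) on chromosome 2 at 24336853 to 24351494, and Il1r2 (ENSMUSG00000026073) on chromosome 1 at 40074079 to 40125231.

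Of 12 negative regulators of the interleukin-1 pathway, 11 were lower in anti-Gr-1 macrophage-like cells, with a median log2 ratio of -0.36 and a counting range of -0.48 to -0.27. As a description of these libraries, none of 10000 expression-matched random lists had a median as low (percentile 0). The members furthest from 0 were Il1r2 (-1.62), Tnip3, an inhibitor of NF-kB signalling (-1.26), Il1rn (-0.51) and Zc3h12a, the cytokine mRNA nuclease Regnase-1 (-0.46). In the same cells Cd209a, a marker of type 2 dendritic cells, was lower (-1.01), as was Tnfsf9 (-1.06), and Tnip3 and Tnfsf9 are each among the leading genes of a type 2 dendritic-like cluster. For monocyte-like and macrophage-like cells summed, the median was -0.22 at percentile 2.72, with 11 of the 12 lower. It was -0.42 over the members above the level of free RNA, -0.63 in female and -0.36 in male cells, and -0.18 in the setting closest to 0. Il1b itself was -1.73 in that sum, in which monocyte-like cells were far fewer in the anti-Gr-1 library. In type 2 dendritic-like cells the list median was -0.05 at percentile 47.1. Over all measured members, the list was lower in other classes too. Its median was -0.53 (range -0.61 to -0.39) in type 1 dendritic-like, -0.27 in gamma-delta type 17-like, -0.34 in regulatory T cell-like and -0.26 in summed T cells. The median of genes with at least 20 CPM in both libraries was itself -0.09, -0.12, -0.14 and -0.14 in these classes, against -0.04 in macrophage-like cells. Over the members above the level of free RNA, the list median was -0.11 in type 1 dendritic-like cells, from 3 members, and -0.09 in summed T cells. Both lay close to the shift of their class.

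Summed over their clusters, macrophage-like cells of the anti-Gr-1 library had less of the genes of recent monocyte origin and more of those of settled tissue macrophages. Both lists share genes with the markers that named the classes, among them Plac8, Fn1, Lyve1 and Folr2, so they are not independent of the naming. Of 11 measured genes of recently recruited monocyte-derived cells, 9 were lower, with a median log2 ratio of -1.13 (range -1.26 to -0.86, percentile 0). Examples were Plac8 (-2.07), the matrix-binding protein gene Thbs1 (-1.81), Fn1, fibronectin (-1.16), and the integrin gene Itgal (-1.13); Vcan had no UMI in the anti-Gr-1 cells, and with it set to the floor of 3 counts the median was likewise -1.13. Over the 10 members above the level of free RNA the median was -1.09. The recruited list was also lower outside macrophages, with medians of -0.70 in summed T cells, -0.61 in dendritic epidermal T cell-like and -0.69 in gamma-delta type 17-like cells, and free RNA of Lyz2 and Fn1 stood at 35.3 against 94.5 and 3.84 against 13.2 CPM. Of 13 measured genes of tissue-resident and repair macrophages, 10 were higher, with a median of 0.31 (percentile 100), also 0.31 with Arg1 at the floor, which had 35 isotype control and no anti-Gr-1 UMIs. Examples were Lyve1, a hyaluronan receptor (0.90), Timd4, a receptor for dying cells (0.65), Retnla (0.62) and Folr2 (0.49), whereas Il10 was -1.05. Efferocytosis and lysosome genes had a median of 0.18 (percentile 99.87). Antigen presentation genes of MHC class II had a median of -0.47 (percentile 0) and NF-kB and TNF response genes one of -0.34 (percentile 0). The MHC class II median was -0.93 in female and -0.34 in male macrophage-like cells. That list was also lower outside macrophages, at -0.84 in female and -0.78 in male summed T cells. Type I interferon response genes had a median of 0.47 (percentile 100), but the median was -0.32 in female cells, with a range of -0.55 to 0.02, and 0.39 in male cells. The immediate early genes that tissue digestion induces had a median of -0.20. Macrophage-like cells came from 3 clusters; in the larger 2 of them, with 517 and 142 or 288 and 119 cells, the recruited list had medians of -1.03 and -0.19 and the interleukin-1 regulator list -0.21 and -0.41. The tissue-resident list was less even, at 0.22 and 0.082 (range -0.013 to 0.15) in these and -0.36 (-0.59 to -0.076) in the third cluster, of 85 and 27 cells. Each of these medians lay under the 0.31 of the clusters summed. In the same order of clusters, MHC class II genes had medians of -0.26, -0.33 and -0.65. Type I interferon response genes had 0.26, 0.18 (-0.055 to 0.47) and 0.74.

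**Figure D2:**
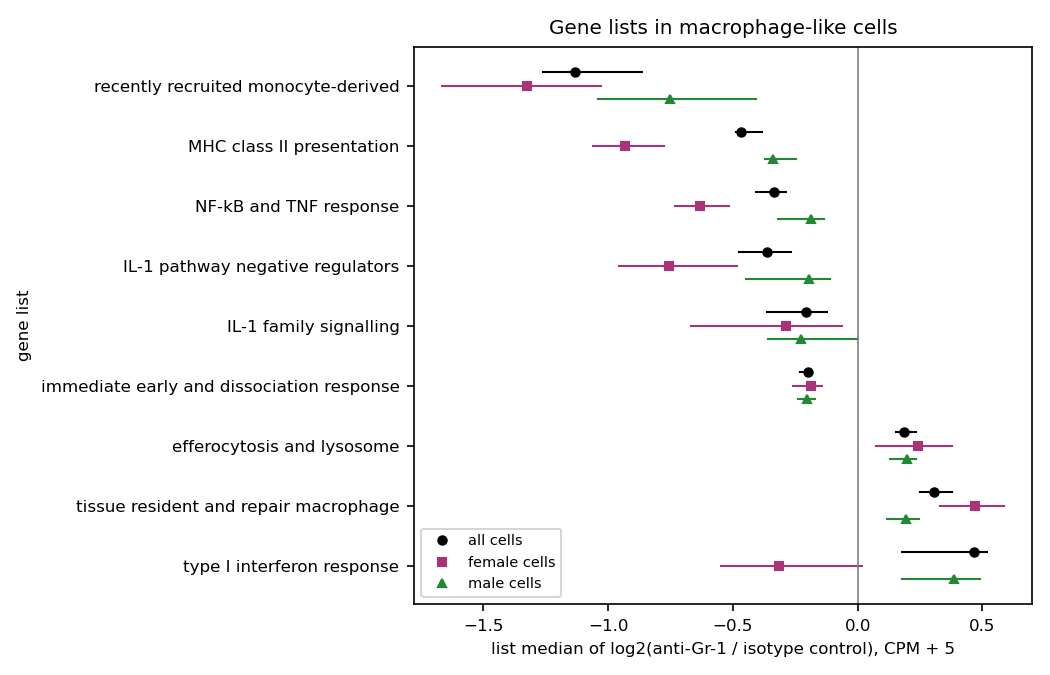
Median log2 ratio of anti-Gr-1 over isotype control (CPM plus 5) for gene lists in macrophage-like cells, in all cells (black), in female cells (purple) and in male cells (green), with lines for the counting range, 1 pooled library each. The recruited list lies at -1.13 and the tissue-resident list at 0.31 over all cells.

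By the rule for named genes, the gene with the highest ratio in macrophage-like cells was Mucl1, a small mucin-like gene, at 706 against 61.6 CPM (log2 3.42 in the pools, 4.25 in female and 6.25 in male cells), followed by Fkbp5, a glucocorticoid-induced chaperone (1.29). The interferon-induced gene Ifi27l2a was also higher (0.73), while the transferrin receptor gene Tfrc (-1.02), the co-stimulatory ligand gene Tnfsf9 (-1.06) and the lectin gene Cd209a (-1.01) were lower. Of these 20 genes, 9 of the 10 higher and 7 of the 10 lower were above the level of free RNA. In female cells 8 of the 10 higher genes had the same direction and in male cells 9, with the adhesion molecule gene Vcam1 at -1.93 in female and 1.68 in male cells. In type 2 dendritic-like cells the sizes were smaller, 0.36 to 0.93 for the higher genes, among them Ccl17, a chemokine that attracts T cells (0.67), which was 0.93 in female but -0.093 in male cells. Slc15a2, a peptide transporter gene, was lower in these cells (-1.10) and so was the lipid carrier gene Apoe (-0.66).

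The type 17 programme was compared across T cells because the series asks about type 17 inflammation. Il17a, the lead cytokine of these cells, was alike in gamma-delta type 17-like cells, at 585 CPM in the isotype control and 570 in the anti-Gr-1 library (ratio 0.974, 0.935 to 1.01). In female cells its ratio was 1.25 (1.16 to 1.35) and in male cells 0.846 (0.798 to 0.896), a difference that was not tested. Its close relative Il17f was lower, at 353 against 461 (ratio 0.767, 0.730 to 0.806), and Il22, a cytokine that acts on keratinocytes, was lower too, at 8.01 against 15.9 (ratio 0.504, 0.366 to 0.686). Il1r1, the signalling receptor for interleukin-1, was higher, at 160 against 136 (ratio 1.17, 1.08 to 1.27). With every cell thinned to 1000 UMIs, Il17a was found in 18.4% of isotype control and 17.7% of anti-Gr-1 gamma-delta type 17-like cells, leaving out 37 and 2 shallower cells; unthinned the shares were 30.5% and 32.7%. In type 2 dendritic-like cells, which should lack Il17a, thinned shares were 0.483% and 0.127%, and the median depths of the 2 classes before thinning were 4991.5 and 10509 UMIs in the isotype control and 6607.5 and 15247 in the anti-Gr-1 library. In the annotation Il17a (ENSMUSG00000025929), Il17f (ENSMUSG00000041872) and Il1r1 (ENSMUSG00000026072) lie on chromosome 1 at 20730905 to 20734496, 20777146 to 20790617 and 40225080 to 40317257.

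Over all T cell classes, the 22 genes of the type 17 programme had a median log2 ratio of -0.08 (range -0.13 to -0.02) at percentile 74.6 of random lists, with 10 higher and 12 lower. Scaling by total UMIs put the median of genes with at least 20 CPM in both libraries at -0.14 in the summed T cells. In the single T cell classes that median was -0.12 to -0.14. The list in summed T cells thus lay slightly above that shift, and it was 0.06 when scaled by the median of gene ratios. Female cells gave 0.18 and male cells -0.20. In gamma-delta type 17-like cells alone the median was -0.11 at percentile 28.4. Of the other lists in summed T cells, scaled in the same way by gene ratios, type 1 genes had a median of 0.19, type 2 genes -0.04, activation genes 0.02, regulatory T cell genes -0.09 and immediate early genes -0.14. Further from 0 were NF-kB and TNF response genes at -0.24, which without that scaling had -0.36 in the pools, -0.35 in female and -0.34 in male cells, and MHC class II genes at -0.51. Type 1 genes, without that scaling, had -0.22 (-0.30 to -0.063) in female and -0.013 (-0.065 to 0.091) in male cells. Type 2 genes then had -0.30 (-0.42 to -0.14) and 0.025 (-0.17 to 0.083).

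Conventional CD4 T cell-like cells had more Il17f and Il17a and less Ifng in the anti-Gr-1 library, while the type 1 cytokine gene Tnf was equal, at 42.2 and 42.1 CPM. Il17f had 117 UMIs against 8, or 57.2 against 5.72 CPM (ratio 10.0, 4.91 to 23.7), and Il17a was 42.5 against 23.6 (ratio 1.80, 1.19 to 2.78). After thinning to 1000 UMIs, Il17f was found in 4.07% of 246 anti-Gr-1 and 1.24% of 241 isotype control cells, leaving out 1 and 7 shallower cells, from 14 and 4 UMIs (ratio 3.43, 1.08 to 14.3). Il17a then had 12 UMIs in 8 cells against 2 UMIs in 1 cell (ratio 5.88, 1.31 to 54.1). Ccr6, a homing receptor of type 17 cells, was 1.02 on the log2 scale, Tnfsf11, the cytokine RANKL, 1.03, and Il13, a type 2 cytokine, 1.22. Ifng, the type 1 cytokine interferon gamma, was lower, at 124 against 220 (log2 -0.80). So were Ly6c2 (-2.21), the granzyme inhibitor gene Serpinb9 (-1.50) and the interferon-induced chemokine gene Cxcl10 (-1.26). Ly6c2 encodes a target of the antibody and stood at 45.0 against 226 CPM, above the level of free RNA. A change within these cells and a loss of those that bear Ly6C cannot be told apart here. The type 17 list had a median of 0.10 at percentile 99.2, and of 0.41 over the members above the level of free RNA. By sex it was 0.38 in female and 0.48 in male cells over all 21 measured members, but 0.30 (0.026 to 0.52) and -0.17 (-0.29 to 0.11) over the 14 members measured in both sexes, while Il17f was higher in both. The type 1 list had a median of -0.35 at percentile 1.99 and the type 2 list one of -0.04. By sex the type 2 list was 0.011 in female and 0.055 in male cells over its 7 measured members, and 0.23 (-0.37 to 0.79) in female and 0.39 (-0.12 to 0.73) in male cells over the 5 measured in both sexes.

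**Figure D3:**
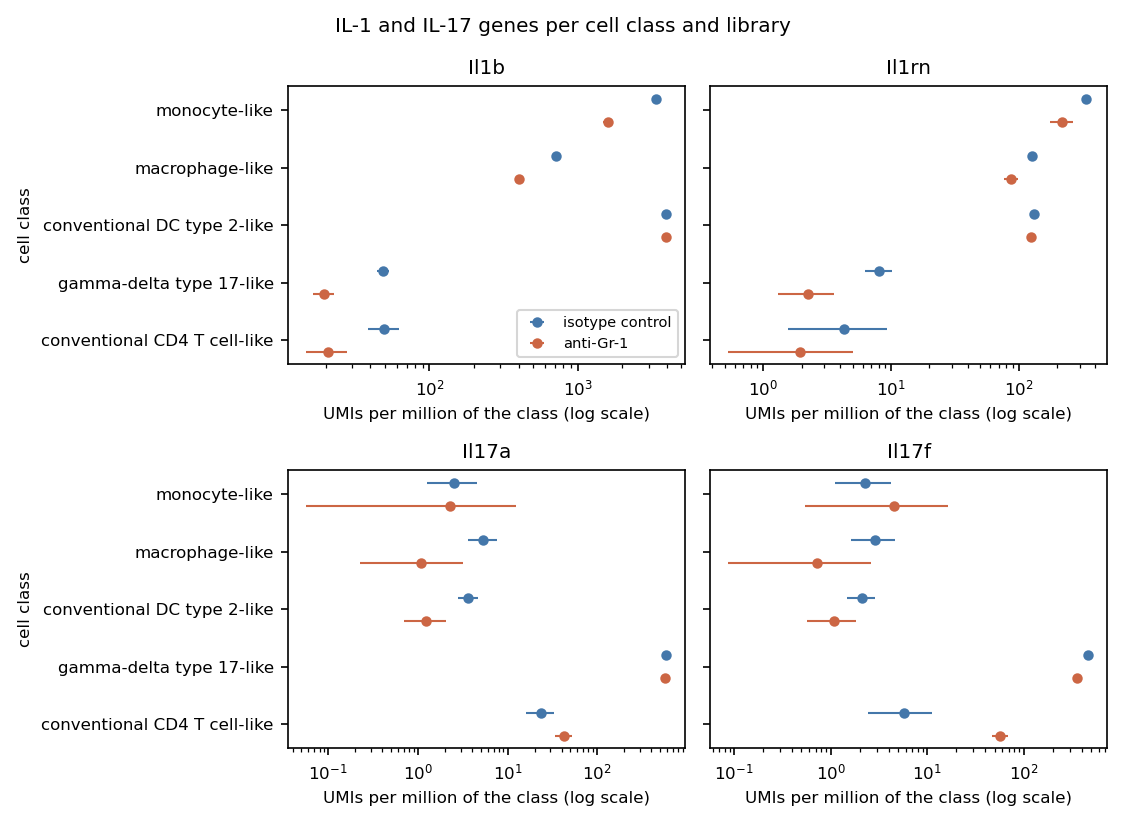
CPM on log axes for Il1b, Il1rn, Il17a and Il17f in 5 cell classes of the isotype control (blue) and anti-Gr-1 (orange) libraries, with 95% exact Poisson bars that cover counting error only. Il17a in gamma-delta type 17-like cells stands at 585 and 570, and Il17f in conventional CD4 T cell-like cells at 5.72 and 57.2.

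In summed T cells, genes that other cells make were lower in the anti-Gr-1 library. The MHC class II genes H2-Ab1 (-0.96), H2-Eb1 (-1.03) and Cd74 (-0.96) and the lysozyme gene Lyz2 (-1.20) were all at or near the level of free RNA. The stress gene Hspa1a, above that level, was lower as well (-0.85), and Slc15a2 was -1.58, with -0.46 in female and -2.00 in male cells. Tsix, transcribed from the X inactivation centre, was -1.17 in the pools but -0.33 in female and -0.39 in male cells, and the pools differed in sex: 51.5% (50.6 to 52.5) of the isotype control cells that could be sexed carried Xist alone, against 24.9% (23.8 to 26.1) in the anti-Gr-1 library. AY036118 had the highest ratio in summed T cells (1.27) and was among the 10 higher genes in every class with named genes. It was 1.17 in macrophage-like, 0.93 in type 2 dendritic-like and 1.32 in gamma-delta type 17-like cells. In conventional CD4 and regulatory T cell-like cells it was 1.13 and 1.39. The cause of a rise shared by these classes was not tested. Other higher genes in summed T cells were Hist1h1e (0.72) and Ubb (0.65). Ltb4r1, a leukotriene receptor, was higher too (0.65 in summed T cells, 0.78 in gamma-delta type 17-like cells), and in the latter Hopx (0.92) and the growth factor gene Areg (0.61). Bcl2a1a, Bcl2a1b and Bcl2a1d, survival genes of nearly identical sequence, were also higher there (1.33, 0.64 and 0.81), and which of them the reads came from is uncertain. In regulatory T cell-like cells Ly6a (0.84) and Ifi27l2a (0.75) were higher, and Il18rap, an interleukin-18 receptor chain (-1.01), and Trat1 (-1.02) were lower. Trat1 and Cd7 are among the leading genes of dendritic epidermal T cell-like clusters, and Cd7 was lower too (-1.16), not above free RNA. Whether RNA of epidermal T cells adds to their levels was not tested. Of the genes named in regulatory T cell-like cells, 5 of the 10 higher and 5 of the 10 lower were above the level of free RNA. Of the genes named in summed T cells, 6 of the 10 higher and 3 of the 10 lower were above the level of free RNA, and each had the same direction in female and in male cells.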

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

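The tests among cells with at least 2000 UMIs, of the mast cell markers and of the interleukin-1 regulators after subtraction and within clusters were chosen after the data were seen, as were the criteria for all comparisons by sex, although the split by sex was planned; the criteria for that subtraction and for the clusters were set before their values were seen. Comparing female with male cells over 161 pairs of class and list, 4 pairs had opposite directions in the sexes, and these differences were not tested. The type 17 programme in summed T cells had a list median 0.37 higher in female than in male cells. In type 2 dendritic-like cells the female minus male difference was -0.092 for immediate early genes and -0.41 for genes of mature neutrophils, and in mast cell-like cells it was 0.23 for immediate early genes. Keratinocyte-like cells, which a CD45+ sort should not keep, made up 1.41% of the isotype control and 0.891% of the anti-Gr-1 cells.

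The scarcity of neutrophil-like and monocyte-like cells in the anti-Gr-1 library could reflect the fewer shallow cells of that library, since neutrophils hold little RNA. Among cells with at least 2000 UMIs the ratios were 0.167 (0.0809 to 0.309) and 0.150 (0.108 to 0.204), which argues against shallow cells as the whole cause. Within each sex the monocyte-like ratio stayed low, and the value with the higher upper end was 0.174 (0.0738 to 0.349), which argues against the mix of sexes. Removal of Ly6C-bearing and Ly6G-bearing cells by the antibody remains the candidate explanation named by the design, as a hypothesis, since each treatment has 1 pool. Loss during the sort and chance differences between pools were not tested.

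The lower MHC class II and Lyz2 levels in T cell classes may come from more free RNA in the isotype control library. Mast cell markers, which T cells do not make, had ratios of 0.567, 0.596 and 0.471 in gamma-delta type 17-like, dendritic epidermal and conventional CD4 T cell-like cells, with upper ends of 0.639, 0.659 and 0.612, but in regulatory T cell-like cells the ratio of 0.703 had an interval of 0.555 to 0.887. This check cannot tell free RNA and a lower level within the T cells apart for these genes, because that interval lies on both sides of the bound of 0.8. The fall was not particular to T cells, though. Dendritic cell genes that include these MHC class II genes had a ratio of 0.507 (0.492 to 0.522) in dendritic epidermal T cell-like cells. In mast cell-like cells it was 0.505 (0.481 to 0.531), a value looked at after the data were seen. The mix of sexes was argued against, since the higher of the ratios in female and male T cells was 0.510 (0.496 to 0.525). Doublets left among the T cells and other differences between the pools of mice were not tested.

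Over all measured members, interleukin-1 regulators were also lower in type 1 dendritic-like (-0.53) and summed T cells (-0.26). Over the members above free RNA they lay close to the general shift of genes in those classes. The lower interleukin-1 regulators in macrophage-like cells might stem from free RNA, from a shift between clusters or from the sexes. After subtraction of the lowest class level the list median was -0.39 (-0.53 to -0.19), which argues against free RNA as the whole cause. Within the smaller of the 2 main clusters it was -0.41 (-0.59 to -0.14), which argues against a shift between clusters. Within each sex it was below 0, and in male cells, where it came closer, it was -0.22 (-0.49 to -0.14) over 11 members and -0.20 (-0.45 to -0.11) over the 10 members measured in both sexes, so the mix of sexes alone does not account for it. A loss of newly recruited macrophages within the clusters is a hypothesis that stays open, as do handling and chance differences between 2 pools. RNA of type 2 dendritic cells in these droplets, whose marker Cd209a was lower too (-1.01), also stays open. Subtraction of the lowest class level would not remove such RNA where it comes from doublets. None of these was tested.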

How the results depend on the processing

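The settings chosen after the data were seen are those named in this part with "added". No paired analysis was possible because each group has 1 pooled library and no number links them. Each library clustered alone formed no neutrophil-like and no monocyte-like cluster in the anti-Gr-1 library, a ratio of 0 that is no count of absent cells, since so few cells may form no cluster of their own. With at least 2000 UMIs (added) the neutrophil-like ratio was 0.167, and marker gates (added) gave monocyte-like ratios of 0.252 and 0.295; these were the highest of 14 neutrophil-like and 16 monocyte-like settings. The T cell ratio was 1.46 with doublets kept, 1.41 with each library alone, 1.23 in female and 1.22 in male cells, 1.28 without neutrophil-like and monocyte-like cells, 1.20 with at least 2000 UMIs (added) and 1.14 outside mixed clusters (added). The mast cell-like ratio reversed to 0.829 with mixed clusters counted under their best-scoring class (added), by the cells this adds. Interleukin-1 regulators had medians of -0.45 with each library alone, -0.63 in female cells, -0.36 in male cells and -0.42 above free RNA (added), and -0.18 was the value closest to 0 among 16 settings. The type 17 list in T cells was 0.011 after thinning, 0.18 in female cells, -0.20 in male cells and 0.063 with median-of-ratios scaling, so its direction depends on the setting. Of the 120 named genes, 30 were named without the filter on low counts and 11 after subtraction of the lowest class level (added). By that subtraction Lyz2 came to 0.15 in summed T cells and 1.21 in regulatory T cell-like cells, which is no evidence of a reversal. The isotype control level subtracted, 94.5 CPM, was that of the regulatory T cell-like cells themselves, so their log2 ratio could not turn negative. In summed T cells it left little of 98.1 CPM. With equal weight per cell the Ly6c2 ratio was 0.223 and the Ly6g ratio 0.879. Except where fewer cells or genes enter by construction, the cause was not tested.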

Other observations

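Clusters outside the named classes also differed between the libraries. A cluster with the eosinophil gene Alox15 and with Serpinb2 held 0.661% of isotype control and 2.33% of anti-Gr-1 cells (ratio 3.52), at a median of 859.5 UMIs, with too few markers found for a name. Clusters led by cycling genes were a myeloid one with 1.88% and 1.24%, a type 1 dendritic-like one with 0.0970% and 0.332%, and lymphoid ones with 1.53% and 2.01% and with 0.303% and 0.452%. Basophil-like cells were 0.710% and 0.479%, mature migratory dendritic-like cells 1.45% and 1.20%, CD8 T cell-like cells 0.249% and 0.399%, and natural killer or group 1 innate lymphoid-like cells 0.849% and 0.970%.

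Over all kept cells, Il1a was lower in the anti-Gr-1 library (ratio 0.342, 0.259 to 0.445) and so was Il23a, a subunit of the cytokine that maintains type 17 cells (ratio 0.640, 0.410 to 0.978, from 72 and 33 UMIs). Il6 was alike (ratio 0.961). In macrophage-like cells, further list medians were -0.21 for interleukin-1 family signalling, -0.19 for type 17 inducing cytokines, -0.35 for neutrophil chemokines, 0.06 for monocyte chemokines, 0.22 for cell cycle genes, -0.20 for hypoxia genes and 0.09 for leukotriene synthesis. The libraries shared 61 barcodes.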
